A study of Mus musculus with 3 samples.

How the data were processed

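Total RNA from 3 biological replicates of OS25 cells, labelled undifferentiated ES cells, was measured on mouse Illumina BeadArrays. Per the labels, RNA was extracted with TRIzol, treated with DNase I and checked on a Bioanalyser, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The deposited table of unprocessed values gives, per the file headers, each probe's intensity (linear mean bead brightness, neither background-subtracted nor normalised) and its detection p-value, which sets a probe against the negative control beads of the same array. Its steps put the smallest nonzero detection p-value at 0.00107. The table that the authors processed holds log2 intensities of 17754 of the 45281 probes. Its 3 columns hold the same values after sorting, to within 0.00036, and follow log2 of the unprocessed intensity (r of 0.999 to 1.00 for each array), which is quantile normalisation with no background subtraction. Limma was used per the submitters' processing notes; its version, the bead summary software and the filter on probes are not given in the sources used here. Set against the detection p-values, the processed table keeps every probe under 0.01 on at least 1 array and 934 others, and none of the 27527 probes outside it was under 0.01 on any array. Of the probes in the processed table, 15045 were assigned to 1 gene, 5 listed several genes and were left out of gene counts, and the rest had no gene name; 2709 of the 17754 (15.3%) were thus not analysed by gene. Genes were matched by their Entrez identifier to the RefSeq annotation, from which only names, gene types and chromosomes were taken. No probe outside the processed table was given a gene name here.

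The main values came from the unprocessed table through neqc in limma 3.58.1 (R 4.3.3): normexp background correction with control statistics inferred from the detection p-values, an offset of 16, quantile normalisation and log2. A probe was detected on an array at a detection p under 0.01 and in the study where this held on all 3 arrays; a gene was detected where any of its probes was. The levels of a gene are those of its probe with the highest mean, and no probe's level was set against another's. The number of arrays (3) limits the precision.

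The tests, the gene lists and the rule for naming genes were fixed before the data were examined. There were 25 lists: pluripotency, LIF response, primed epiblast, 2-cell-like, neuroectoderm, mesoderm, endoderm, trophectoderm, germ cell, fibroblast, blood and immune, liver and other adult tissue, H4K16 acetyltransferase complexes, other histone acetyltransferases, histone deacetylases, acetyl-lysine readers and remodellers, Polycomb, H3K4 methylation (trithorax), DNA methylation, Hox, cell cycle, cell cycle inhibitors and p53 targets, stress response, housekeeping, and X dosage and Y-linked. A name in the H3K4 methylation list that matched no RefSeq gene was left out. Named genes were the first 4 measured members of each list, all detected members where there were 5 or fewer, all undetected members where there were 5 or fewer, and the 10 detected genes with the widest range between arrays. Each list with at least 3 measured genes was tested against the other named genes, the pluripotency list against each lineage list, and X-linked against autosomal genes, by two-sided Fisher's exact tests. P-values were adjusted by Benjamini and Hochberg's method over the lists and over the lineage comparisons, with a threshold of 0.05. Genes are not independent replicates, so these tests describe the lists on these arrays. Because named genes were mostly detected ones by construction of the processed table, every test among them starts from a high share. Whole lists against all other protein-coding genes in RefSeq were therefore added as an alternative after the data were examined; a gene with no named probe counts there as not detected. Further lists of 31 ES cell genes and 27 fibroblast genes were written after the first lists had been read and before the values of their own genes were, leaving out fibroblast genes already seen; detection on them was compared among genes with a named probe. Intervals of shares are 95% Clopper-Pearson intervals.

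Replicates were compared by Pearson's and Spearman's correlation across detected probes and by the range over arrays. List shifts were set against 10000 random lists matched on mean expression in 20 bins. The alternatives fixed in advance were detection p under 0.05 or 0.001, detection on at least 1 array, other rules for genes with several probes, probes as units, quantile normalisation alone, no normalisation between arrays, the processed values of the authors, no filter on dim probes, the mean of a gene's probes, and each replicate left out. Computation used Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6. The steps were tested on simulated data. Of 13777 probes given signal, 98.8% were called detected on all 3 arrays, and none of the probes without signal was. A log2 shift of 1 given to 200 probes on 1 array was recovered as 0.92. Signal was given to the probes detected in the real data, near their observed levels, so the 98.8% was largely fixed in advance. Background was drawn independently for each array, and the noise set between replicates was below the median SD of the real arrays. The simulation thus checks that the steps run, and not how often detection is right on these arrays.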

Results

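Gene expression was measured in OS25 cells, a mouse embryonic stem (ES) cell line, on 3 Illumina BeadArrays, each carrying RNA from 1 biological replicate. The labels give 1 group, undifferentiated ES cells, grown in medium with 10% foetal calf serum, 1000 units/mL of leukaemia inhibitory factor (LIF) and hygromycin. The arrays accompany a study of the acetylation of lysine 16 on histone H4 (H4K16) in undifferentiated ES cells. With a single group, the design implies 3 kinds of comparison: which gene groups were detected, whether genes of the ES cell state were detected more often than genes of other lineages, and how far the replicates differed. The median intensity was 80.7 on replicate 1, 79.8 on replicate 2 and 74.9 on replicate 3, and 15865, 15206 and 14515 of 45281 probes were above background on those arrays. A probe was called detected where its detection p was under 0.01 on all 3 arrays, which held for 13777 probes (30.4%). Of 9678 genes with a named probe, 7955 (82.2%) were detected. That share is high because gene names were used only for the 17754 probes in the authors' table of processed values, which holds every probe above background on at least 1 array and 934 others. A gene with no named probe therefore either lacks a probe, has an unnamed one or was at background on all 3 arrays. Expression is given as normalised log2 intensity, mean ± SD over n = 3 arrays.

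The first question was whether the arrays labelled undifferentiated ES cells carried the transcripts of that state. Of 30 genes characteristic of naive ES cells, 5 were detected on all 3 arrays: the Krüppel-like factors Klf4 (7.47 ± 0.87, n = 3), Klf2 (7.64 ± 0.09, n = 3) and Klf5 (9.40 ± 0.71, n = 3), the T-box factor Tbx3 (8.06 ± 0.24, n = 3) and the Nodal antagonist Lefty1 (5.93 ± 0.37, n = 3). Klf2, Klf4, Klf5 and Tbx3 are also transcribed in cells other than ES cells. Another 4 genes had a named probe and were not detected on all 3 arrays, among them Zfp42, which encodes the ES cell marker REX1 (detection p of 0.00107, 0.0374 and 0.0203 on replicates 1, 2 and 3), and Tfcp2l1, a factor of the naive network (0.0203, 0.248 and 0.512). The others were Fbxo15, above background on replicate 1 alone, and the DNA demethylation enzyme gene Tet1, likewise above background on replicate 1 alone. The remaining 21 genes had no named probe, and they include the core regulators Pou5f1, Nanog, Sox2 and Esrrb, named here after this was seen. The share detected was 55.6% among named genes against 82.2% of the other genes, which did not pass (two-sided Fisher's exact test, adjusted p = 0.341), nor did 16.7% of the whole list against 35.8% (two-sided Fisher's exact test, adjusted p = 0.0549). Unnamed probes made up 15.3% of the authors' processed table, and none of the 27527 probes outside it was above background on any array. That share is of probes within the table, so it cannot be set against the 21 of 30 genes with no named probe. A gene that lacks a probe cannot be told from one at background. These genes alone do not settle the label, which is taken up with further lists below. The samples are called the arrays labelled undifferentiated ES cells from here on.

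Genes of fibroblasts and of the body axis were also detected. Of 16 fibroblast genes, 10 were detected, with the type I collagen gene Col1a1 at 11.90 ± 0.12 (n = 3), its partner chain Col1a2 at 6.93 ± 0.60 (n = 3) and the surface protein gene Thy1 at 8.71 ± 1.66 (n = 3). Col3a1 (detection p of 0, 0.00427 and 0.0256) and the proteoglycan gene Dcn (0, 0 and 0.0128) were above background on replicates 1 and 2 and not on replicate 3. Of 28 Hox genes, which pattern the body axis and are held silent by Polycomb proteins in ES cells, 14 were detected, among them Hoxa5 (8.61 ± 0.43, n = 3), Hoxa7 (8.81 ± 0.04, n = 3) and Hoxa9 (5.69 ± 0.31, n = 3). Cdkn2a, a cell cycle inhibitor gene that Polycomb proteins also repress, was detected at 9.96 ± 0.25 (n = 3).

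Against the lineage lists, no difference in detection of the pluripotency list passed among named genes. Among genes with a named probe, 5 of 9 pluripotency genes were detected (55.6%) against 10 of 12 fibroblast genes (83.3%), a difference of −27.8 percentage points (two-sided Fisher's exact test, adjusted p = 0.843 over 9 comparisons). The difference from the Hox list was −22.2 points, and those from the primed epiblast, trophectoderm, and blood and immune lists −11.1 points each. The pluripotency share was the higher one against mesoderm (30.6 points), liver and other adult tissue (55.6 points), neuroectoderm (5.56 points) and endoderm (5.56 points). All 9 adjusted p by two-sided Fisher's exact tests were between 0.843 and 1. Counting every member of both lists, and those with no named probe as not detected, a denominator chosen after the data were examined, 16.7% of the pluripotency list and 62.5% of the fibroblast list were detected, a difference of −45.8 percentage points (two-sided Fisher's exact test, p = 0.00278, adjusted p = 0.0306 over 11 comparisons). On that denominator the difference from the Hox list was −33.3 percentage points (adjusted p = 0.0614). Without replicate 1 the pluripotency count was still 5 of 30 and the fibroblast count 10 of 16, while the Hox count was 16 of 28 and its adjusted p passed the threshold (0.0153), as it did without replicate 3 (0.0127). The calls on whole lists rest largely on genes with no value (21 of the 30 pluripotency, 4 of the 16 fibroblast and 10 of the 28 Hox genes).

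**Figure D1:**
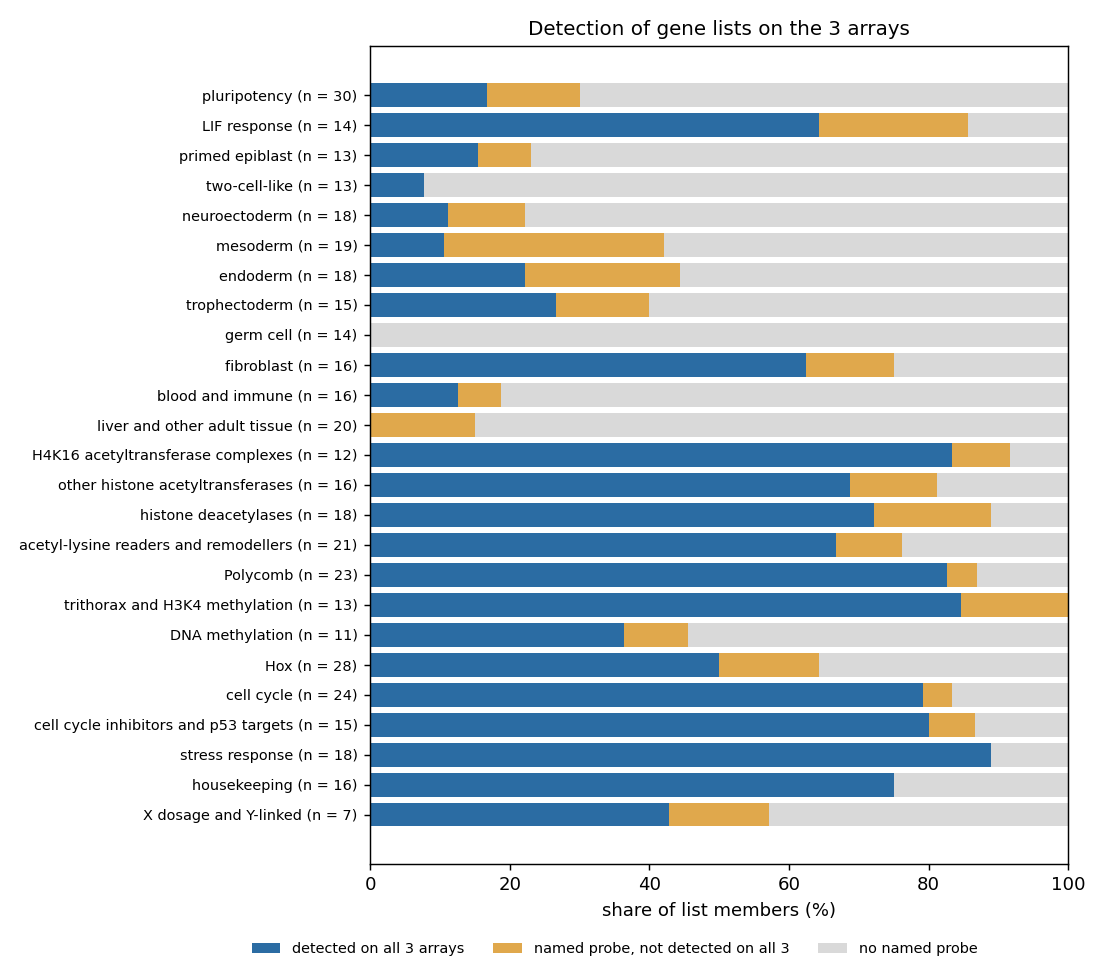
Each bar splits the members of 1 gene list (n members) into those detected on all 3 arrays, those with a named probe not detected on all 3, and those with no named probe, as a share in percent. The pluripotency bar is detected to 16.7% and the fibroblast bar to 62.5%.

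Mesoderm was the only list whose difference from the other genes passed among named genes: 2 of 8 were detected (25%) against 82.2% (two-sided Fisher's exact test, p = 0.000637, adjusted p = 0.0146 over 23 lists). The detected members were Tbx5 (5.63 ± 0.27, n = 3) and the growth factor receptor gene Pdgfra, at 9.59, 6.07 and 5.84 on replicates 1, 2 and 3. Gsc, a gene of the embryonic organizer, was at background on replicate 1 (4.67) and above it on replicates 2 (8.44) and 3 (8.77). Named genes were mostly those above background on some array. The mesoderm call therefore describes genes not detected on every array, and it does not show that mesoderm genes were absent. The mesoderm call ended when a gene counted as detected on at least 1 array (87.5%, adjusted p = 0.957), when every probe of a gene had to be detected (adjusted p = 0.185) and with whole lists as the denominator (10.5%, adjusted p = 0.0502). In the endoderm list 4 of 8 named genes were detected (adjusted p = 0.293), including Gata6 (10.11 ± 0.61, n = 3), Dab2 (10.17 ± 0.41, n = 3) and the basement membrane collagen gene Col4a1 (11.68 ± 0.24, n = 3). In the trophectoderm list 4 of 6 were detected (adjusted p = 0.669), with Gata3 at 9.65 ± 0.18 (n = 3) and the receptor gene Fgfr2 at 10.26 ± 0.92 (n = 3). The neuroectoderm list had 2 of 4 detected (adjusted p = 0.486): Nes (8.95 ± 0.59, n = 3) and Map2 (7.78 ± 0.56, n = 3), both of the cytoskeleton. The primed epiblast list had 2 of 3 (adjusted p = 0.785), Dnmt3b (7.74 ± 0.60, n = 3) and Sall2 (7.41 ± 0.70, n = 3), and the remaining named member, Pou3f1, was above background on replicate 1 (7.72) and not on replicates 2 (4.57) and 3 (4.70). Blood and immune genes had 2 of 3 (adjusted p = 0.785), Cd14 (6.86 ± 0.16, n = 3) and Itga2b (6.21 ± 0.14, n = 3), and 13 of that list's 16 genes had no named probe. None of 3 named genes of liver and other adult tissue was detected on all 3 arrays (adjusted p = 0.0648), and this passed at a detection p under 0.05 (adjusted p = 0.0144), without replicate 1 (adjusted p = 0.0484) and without replicate 3 (adjusted p = 0.0382), by two-sided Fisher's exact tests. It turned with detection on at least 1 array, when all 3 counted as detected (100%, two-sided Fisher's exact test, adjusted p = 1), since Krt14 (7.59), Lor (5.90) and Amy2a5 (5.25) were above background on replicate 1 alone. None of the 3 could then count as detected without replicate 1 or without replicate 3, so those calls were fixed by that pattern. They are no evidence that such genes were absent. The other 17 genes of that list had no named probe. None of 14 germ cell genes and 1 of 13 genes of the 2-cell embryo stage had a named probe, the latter being Eif1a (10.67 ± 0.82, n = 3), and neither list was tested among named genes.

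H4K16 acetylation is the subject of the series. Genes of its acetyltransferase complexes, of other histone acetyltransferases and deacetylases, and of acetyl-lysine readers and remodellers were mostly detected on the arrays labelled undifferentiated ES cells. Of 12 members of the acetyltransferase complexes, 11 had a named probe and 10 were detected, among them the H4K16 acetyltransferase gene Kat8 (7.68 ± 0.13, n = 3) and the MSL complex genes Msl1 (8.36 ± 0.10, n = 3) and Msl2 (7.69 ± 0.60, n = 3). Msl3, another gene of that complex, was above background on replicates 1 and 3 and not on replicate 2 (detection p of 0.00534, 0.0107 and 0.00214 on replicates 1, 2 and 3). Other histone acetyltransferases were detected at 11 of 13 named genes, including Kat2a (8.85 ± 0.35, n = 3) and Kat5 (7.70 ± 0.28, n = 3, with 1 of its 2 probes detected). Deacetylases were detected at 13 of 16, including Hdac2 (11.09 ± 0.13, n = 3) and Hdac3 (10.46 ± 0.23, n = 3), while Hdac8, Hdac11 and Sirt6 were not detected on all 3 arrays. Acetyl-lysine readers and remodellers were detected at 14 of 16, with the bromodomain genes Brd2 (10.81 ± 0.09, n = 3) and Brd3 (10.47 ± 0.32, n = 3). Among named genes, no difference of these 4 lists from the other genes passed (two-sided Fisher's exact tests, adjusted p between 0.949 and 1). With whole lists as the denominator, where a gene with no named probe counts as not detected, all 4 were detected more often than other protein-coding genes (35.8%), at 83.3%, 68.8%, 72.2% and 66.7% in the order given (two-sided Fisher's exact tests, adjusted p = 0.00371, 0.0174, 0.00677 and 0.0115). That comparison, here and below, mixes having a named probe with being detected. Housekeeping genes passed it too (75%), so it does not set these 4 lists apart.

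Other chromatin regulators and growth genes were also widely detected. Polycomb genes were detected at 19 of 20 named members, with the methyltransferase gene Ezh2 at 9.92 ± 0.16 (n = 3) and its partner Suz12 at 11.51 ± 0.06 (n = 3); Ezh1 was not detected on all 3 arrays. The H3K4 methylation list was detected at 11 of 13, including Kmt2a (10.55 ± 0.09, n = 3). Of the DNA methylation genes 4 of 5 were detected, including the maintenance genes Dnmt1 (10.06 ± 0.21, n = 3) and Uhrf1 (11.51 ± 0.20, n = 3). Cell cycle genes were detected at 19 of 20, with Ccnd1 at 10.98 ± 0.83 (n = 3); cell cycle inhibitors and p53 targets at 12 of 13; stress response genes at 16 of 16, with the chaperone gene Dnajb1 at 11.10 ± 0.04 (n = 3); and housekeeping genes at 12 of 12, with Gapdh at 12.98 ± 0.08 (n = 3). Genes of the LIF pathway, which sustains ES cell self-renewal, were detected at 9 of 12, including the receptor subunit gene Il6st (7.72 ± 0.09, n = 3), while Lifr was above background on replicates 1 and 3 alone. Among named genes, no difference of these lists from the other genes passed (two-sided Fisher's exact tests, adjusted p between 0.430 and 1). With whole lists, Polycomb (82.6%, adjusted p = 6.99e-05), H3K4 methylation (84.6%, 0.00218), cell cycle (79.2%, 0.000148), inhibitors and p53 targets (80%, 0.00253), stress response (88.9%, 6.99e-05) and housekeeping genes (75%, 0.00684) were detected more often than other protein-coding genes by two-sided Fisher's exact tests. LIF pathway (64.3%, adjusted p = 0.0640) and DNA methylation genes (36.4%, adjusted p = 1) did not pass there (two-sided Fisher's exact tests).

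Expression of the X chromosome, which the MSL complex raises in male flies, was addressed by detection alone. Xist, the RNA that coats an inactive X, was at background on all 3 arrays with each of its 4 probes, and the Y-linked genes Eif2s3y (8.19 ± 0.93, n = 3) and Uty (5.85 ± 0.20, n = 3) were detected. With Rlim, 3 of the 4 named genes of the X dosage and Y-linked list were detected (adjusted p = 0.785). Of 291 X-linked genes 230 (79.0%) were detected, and of 9369 autosomal genes 7710 (82.3%), a difference of −3.25 percentage points that did not pass (two-sided Fisher's exact test, p = 0.161).

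Among genes detected on all 3 arrays, the 10 with the widest range between replicates were Igtp, Igfbp4, Oasl2, Gbp2, Gbp3, Irgm2, Tapbp, Ankrd1, H2-Ab1 and Psmb9. Igtp, an interferon-inducible GTPase gene, was at 12.55, 7.64 and 10.98 on replicates 1, 2 and 3. Another of these GTPase genes, Gbp2, was at 12.27, 7.66 and 10.46, and the immunoproteasome gene Psmb9 at 12.18, 8.09 and 10.36. H2-Ab1, of the major histocompatibility complex class II, was at 11.25, 7.24 and 7.07, and the growth factor binding protein gene Igfbp4 at 10.45, 6.31 and 5.75. Ankrd1, a target of the Hippo pathway, went the other way, at 7.52, 11.49 and 11.83. Replicate 1 was the highest array in 9 of the 10 genes. The rule left out genes at background on any array, such as Dcn, singled out after its values were seen, which was at 12.28 on replicate 1, 6.77 on replicate 2 and not above background on replicate 3, so that its range has only a lower bound. The cell cycle inhibitor gene Cdkn1a, a p53 target, was at 8.06, 11.95 and 11.15.

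**Figure D2:**
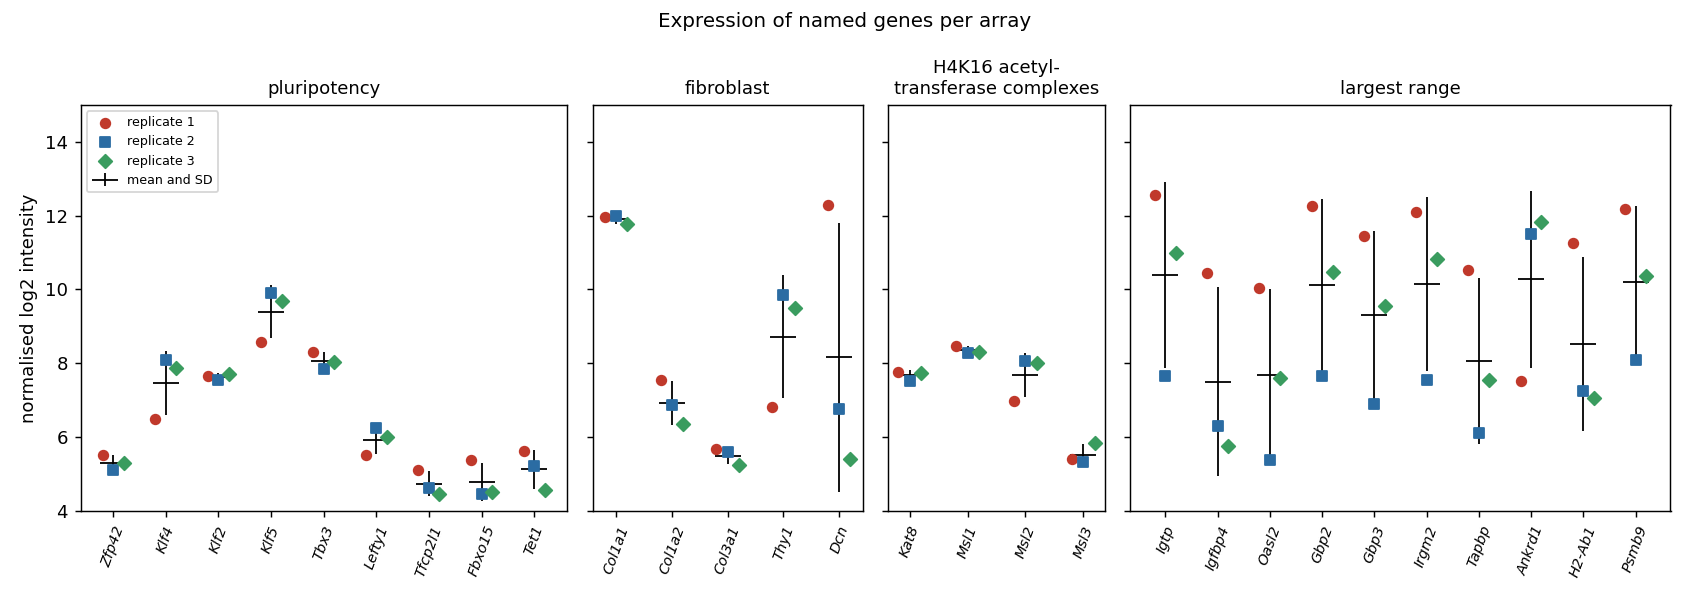
Normalised log2 intensity of single genes on each array (coloured symbols), with the mean and SD over n = 3 arrays in black, for 4 sets of genes. Kat8 and Msl1 lie close together on the 3 arrays, while Igtp runs from 7.64 on replicate 2 to 12.55 on replicate 1.

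Across 13777 detected probes, which are not independent replicates, Pearson's correlation was 0.949 between replicates 1 and 2, 0.951 between 1 and 3, and 0.990 between 2 and 3, and no probe had the same intensity on any pair of arrays. The median SD per probe was 0.22 log2 units, and 1337 probes (9.70%) spanned over 2-fold. In 1229 of these (91.9%) replicate 1 was the array farthest from the middle value. Without replicate 1, 79 probes spanned over 2-fold and the median SD was 0.10.

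Gene lists shifted with the array as well. On each array, the median deviation of a list's detected genes from their mean over the 3 arrays was set against 10000 random lists of the same size and similar expression. Cell cycle inhibitors and p53 targets stood at −0.57, 0.43 and 0.20 on replicates 1, 2 and 3 (12 genes). Endoderm genes stood at 0.59, −0.27 and −0.31 (4 genes), and the X dosage and Y-linked genes at −0.63, 0.29 and 0.34 (3 genes). Each of these lists lay outside the central 95% of random lists on every array. Without normalisation between arrays the value of the inhibitors and p53 targets on replicate 3 was −0.0244, when all detected genes stood at −0.22 there. Fibroblast genes stood at −0.29, 0.22 and 0.17 (10 genes), also outside, but with dim probes kept the signs on replicates 1 and 3 turned (0.0886 and −0.0241). Pluripotency genes stood at −0.41, 0.32 and 0.09 (5 genes), outside on replicates 1 and 2, and with dim probes kept the signs there turned (0.21 and −0.10). In such short lists 1 gene sets the median. The pluripotency values are those of Lefty1. On replicates 1 and 2, Klf4 and Klf5 shifted the same way as Lefty1, and Klf2 and Tbx3 the other way. The X dosage and Y-linked values are those of Rlim. Eif2s3y went with Rlim, while Uty stood at −0.13, −0.10 and 0.23, opposite in sign on replicate 2. In the endoderm list, Gata6, Dab2 and Pdgfra went with the median and Col4a1 against it (−0.25, 0.23 and 0.02). Of the named inhibitors, Cdkn1a went with its list and Cdkn1c against it (1.02, −0.29 and −0.73). Cdkn2a went with that list on replicates 1 and 3 and against it on replicate 2. H4K16 acetyltransferase complexes (0.06, −0.06 and 0.02, 10 genes) and housekeeping genes (−0.01, −0.02 and 0.02, 12 genes) lay inside on every array. In all, 19 of 54 values from 18 lists lay outside. Counted over the remaining arrays, and so over fewer values, 4 did without replicate 1, 12 without replicate 2 and 12 without replicate 3. Each deviation is from the gene's own mean, so a shift on 1 array is balanced by opposite ones on the others. The values of a list on the different arrays are therefore not independent. These values describe the arrays only, since replicates of 1 group carry no contrast.

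**Figure D3:**
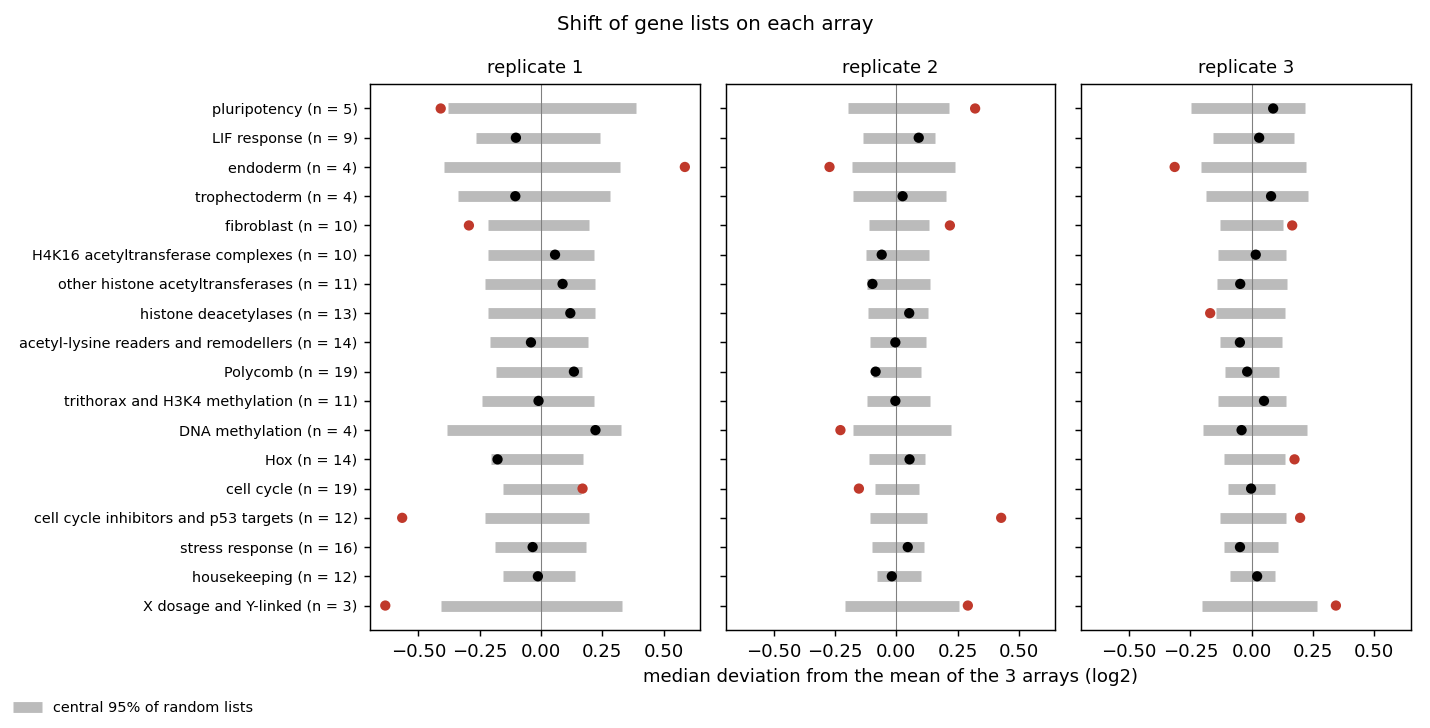
Median deviation of each list's detected genes (n genes) from their mean over the 3 arrays, in log2 units, for each array; grey bars span the central 95% of 10000 random lists, and red points lie outside. Cell cycle inhibitors and p53 targets lie at −0.57 on replicate 1 and 0.43 on replicate 2.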

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

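This result was chosen after the data were seen. Of the probes detected on all 3 arrays, 1852 carried no gene name and entered none of the gene comparisons, so a signal above background stands in data that the comparisons did not use. A gene whose probes are all among them counts as having no named probe. No explanation for their number was tested.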

How the results depend on the processing

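Whole lists as the denominator were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the design has 1 group. The counts of detected probes and genes stayed within 1.5 times under every alternative run, and neither the X-linked difference nor the comparison of the pluripotency list with the other genes crossed the threshold or changed direction. Of the tested results, 49 values lay level with the compared share or on its other side from the main value, and 1 of them passed the threshold, that of the deacetylases with whole lists. The mesoderm call (25%) was lost with detection on at least 1 array (87.5%), with all probes of a gene required (25%) and with whole lists (10.5%). The liver and adult tissue list stayed at 0% but passed at a detection p under 0.05, without replicate 1 and without replicate 3. The share was 0% to 0% with each replicate left out. Its 3 named genes were above background on replicate 1 alone, so the calls with a replicate left out were fixed beforehand. The list passed with whole lists too (0%), where 17 of the 20 genes have no value and the call rests on them. With detection on at least 1 array it turned (100%). Whole lists put these shares past the threshold: H4K16 acetyltransferase complexes 83.3%, other acetyltransferases 68.8%, deacetylases 72.2%, readers and remodellers 66.7%, Polycomb 82.6%, H3K4 methylation 84.6%, cell cycle 79.2%, inhibitors and p53 targets 80%, stress response 88.9%, housekeeping 75%, and the pluripotency minus fibroblast difference of −45.8 points; the denominator of mostly detected genes is gone there by construction, and the difference rests largely on genes with no value. The germ cell list (0%) lay past it too, but its count was fixed, as none of its 14 genes had a named probe. The remaining changes of direction, none past the threshold, were these. With whole lists they were LIF response 64.3%, DNA methylation 36.4%, Hox 50%, X dosage and Y-linked 42.9%, and pluripotency minus primed epiblast 1.28, endoderm −5.56 and blood and immune 4.17 points. With detection on at least 1 array they were LIF response, primed epiblast, liver, deacetylases, DNA methylation and Hox, all at 100%, H3K4 methylation 92.3%, and pluripotency minus trophectoderm 5.56, blood and immune 22.2 and liver −11.1 points. At a detection p under 0.001 they were DNA methylation 80% and pluripotency minus neuroectoderm −5.56. At a detection p under 0.05 they were LIF response 91.7%, blood and immune 100%, deacetylases 93.8%, readers 87.5%, H3K4 methylation 84.6%, and pluripotency minus primed epiblast 0 and endoderm −8.33 points. With all probes of a gene required they were LIF response 75%, fibroblast 66.7%, deacetylases 81.2%, readers 68.8%, DNA methylation 80%, inhibitors and p53 targets 61.5%, X dosage and Y-linked 75%, and pluripotency minus neuroectoderm −5.56, endoderm −5.56 and blood and immune 11.1 points. With probes as units they were fibroblast 61.5%, readers 75.8%, DNA methylation 80%, and inhibitors and p53 targets 78.6%. Leaving out each replicate gave 83.3% to 100% for fibroblast, 77.8% to 88.9% for Hox, 75% to 83.3% for LIF response, 81.2% to 93.8% for deacetylases, and −6.94 to 5.56 points for pluripotency minus endoderm. The mean correlation between replicates was 0.949 to 0.991 with each replicate left out, the median SD 0.10 to 0.23, probes over 2-fold 79 to 1095, and list values outside the random range 4 to 12, each moved most without replicate 1. Probes over 2-fold (1337) numbered 732 with quantile normalisation alone, 2395 without normalisation between arrays, 703 with the authors' values and 2043 with dim probes kept, when the median SD was 0.10. Without normalisation between arrays the shifts on replicate 3 turned for fibroblast (−0.0157), Hox (−0.0481), and inhibitors and p53 targets (−0.0244). All detected genes stood at −0.22 there. With dim probes kept, the pluripotency shift turned on replicates 1 (from −0.41 to 0.21) and 2 (from 0.32 to −0.10), and the fibroblast shift on replicates 1 (0.0886) and 3 (−0.0241). Of the alternatives for single genes' levels and list shifts, 849 of 1084 moved by less than the spread between replicates. Other than where stated, the cause was not tested. Detection is limited by genes with no named probe (21 of the 30 pluripotency genes) and by probes near background (4 of the 30 had a named probe not detected on all 3 arrays).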

Other observations

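The tests on normalisation, feeder cells, another cell type and immune cells were chosen, or limited to genes with a named probe, after the results were seen; those on naming gaps, probe noise and the interferon genes of replicates 2 and 3 were set before their own results were seen, though after the patterns they address.

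Interferon response genes differed between all 3 arrays labelled undifferentiated ES cells. A further 42 genes induced by interferon were listed from textbook knowledge, leaving out those already seen to vary. Of these, 30 had a named probe and 24 were detected, with replicate 1 highest in 21 and replicate 2 lowest in 22. Tap1, a gene of antigen presentation, was at 9.97, 7.27 and 8.53 on replicates 1, 2 and 3. The deubiquitinase gene Usp18 was at 9.49, 6.99 and 8.22, and the transcription factor gene Stat2 at 8.37, 6.32 and 7.54. Samd9l was lowest on replicate 1 (8.66, 9.07 and 9.52). The median deviation of the 24 genes was 0.67, −0.74 and 0.07 on the 3 arrays, and without normalisation between arrays it was 0.95, −0.78 and −0.16, when all detected genes stood at 0.26, −0.04 and −0.22.

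Few ES cell genes, and many fibroblast genes, were detected on the arrays labelled undifferentiated ES cells, so 31 further ES cell genes and 27 further fibroblast genes were listed without sight of their values. Naming gaps that fall on genes of every kind alike are argued against, since 25.8% of the further ES cell genes had a named probe against 88.9% of the further fibroblast genes (8 of 31 and 24 of 27; two-sided Fisher's exact test, p = 1.2e-06), but a gap confined to ES cell genes stays open for those with no named probe. Fibroblast feeder cells mixed into ES cells cannot be told apart from ES cell genes without a named probe. Of the 8 further ES cell genes with one, 1 was detected on all 3 arrays (12.5%, Fabp3). The Clopper-Pearson interval of 0.316% to 52.7% reaches past the 50% set as the bound. The labels name no feeder cells. Hygromycin was in the medium, but which cells would resist it was not tested, so it does not separate these explanations. Cells of another type than the label names may account for the pattern: among genes with a named probe, detection of the further ES cell genes minus that of the further fibroblast genes (24 of 24) was −87.5 percentage points (two-sided Fisher's exact test, p = 2.38e-06), although named genes are mostly detected ones and ES cells also express some fibroblast genes, such as Lgals1 (13.99 ± 0.07, n = 3). Differentiation of the ES cells in culture, and which cells these may be, were not tested.

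Replicate 1 stood apart from replicates 2 and 3. Normalisation between arrays is argued against as the whole cause, because the rank correlation of the deposited intensities, which no scaling of an array alters, was higher between replicates 2 and 3 than in the better of the pairs with replicate 1 by 0.0491. Noise that strikes each probe independently is argued against, because the deviations of replicate 1 went together in pairs of probes of the same gene (correlation 0.819 across 2856 pairs, bootstrap interval 0.797 to 0.840). The test cannot address a bias of amplification or labelling, which acts on whole transcripts and would move both probes of a gene alike. Such a bias stays open, as do differences between the cultures or in the RNA before labelling. The design gives no group against which a biological explanation could be tested.

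The interferon difference may be separate from whatever sets replicate 1 apart. Over the 24 detected genes of the further list, replicate 3 exceeded replicate 2 by a median of 0.79 log2 units, outside the central 95% of random lists (−0.11 to 0.09) and in 23 of the 24 genes, although replicates 2 and 3 were otherwise the closest pair. That direction had already been seen on the same arrays in Igtp, Gbp2 and Psmb9. Random lists draw genes independently, so their range is too narrow for genes that are induced together. The values therefore describe these arrays and are weak evidence of a separate difference. Immune cells in the cultures cannot be told apart from the cultured cells as the source. Of the 16 blood and immune genes, 13 had no named probe. Of the other 3, Cd14 (6.86) and Itga2b (6.21) were detected (66.7%, Clopper-Pearson interval 9.43% to 99.2%). With 3 genes the interval is wide whichever of them are detected, so this share could not have decided the question. Detection on all 3 arrays also does not address a difference between arrays. An interferon response of the cultured cells that differed in strength is a hypothesis left open, with no treatment in the labels to test it on.

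The authors' processed table holds 934 probes at background on all 3 arrays, of which 648 had a gene name, for 618 genes. They include all 4 probes of Xist.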
